A study of Mus musculus with 18 samples.

How the data were processed

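Total RNA was sequenced from splenic T cells of mouse donors with intact Wapl (WT) or without it (KO), taken from recipients on day 7 after transplantation. Per the labels, recipients received 9.5 Gy (syngeneic) or 8 Gy (allogeneic), T cell depleted donor marrow and donor T cells. T cells were enriched from spleen and sorted as live, CD3 positive and CD45.2 positive cells, and each library used 100 ng of RNA from 2 to 4 pooled mice, with ribosomal RNA depletion. The labels name female C57BL/6 donors and do not separately give the sex of the KO donors, the Cre line or the deleted exons.

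The values used were expected counts per gene, as deposited by the authors, whose processing notes name TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff 2.2.1 and the mouse genome build GRCm38. Which of these tools made the counts, and with which annotation and strand setting, is not given in the sources used. Between 94.5 and 95.0% of the values of a library were whole numbers, and totals differed between libraries, so the values were taken as unscaled estimated counts. They were rounded before the fit. The table held 46073 genes, and 45139 identifiers matched GENCODE release M21 of the same build, from which positions were taken. Wapl stands in the table under the symbol Wapal.

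The labels describe 18 samples, and the columns of 12 of them could be matched, 3 in each of 4 groups. The other 6 columns carry the identifiers of the allogeneic samples with the prefix allo. The columns without the prefix were used as the allogeneic libraries, because their names match the identifiers in the sample titles. Which samples the prefixed columns hold was not tested. The prefixed columns match no other sample by name and were not used here. The naive samples were therefore not analysed here, and neither were the comparisons and interactions that need them. The design planned for all 18 samples left 12 residual degrees of freedom, and the fit of 12 libraries had 8. The comparison of allogeneic with syngeneic libraries in KO was added after this was seen. Syngeneic KO libraries are labelled syngeneic by transplant type, but their cell type field names the recipient strain of the allogeneic samples. They were grouped by transplant type.

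The design, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. One edgeR 4.0.16 model (R 4.3.3, limma 3.58.1) with a mean per group was fitted to all 12 libraries. It used TMM scaling, the filterByExpr filter (count minimum 10, 18447 genes kept) and a robust quasi-likelihood fit. The biological coefficient of variation was 0.249. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called, by two-sided quasi-likelihood F tests. Standard errors were the log2 fold change divided by the square root of the F statistic. CPM values are counts scaled by TMM-adjusted library sizes, and group values are means ± SD. All adjusted p values of single genes come from edgeR unless DESeq2 1.42.0 is named.

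The 27 lists covered cohesin and its regulators, S phase, G2/M, p53 targets, naive, effector, inhibitory receptor, regulatory, type 2 helper and type 17 helper T cells, trafficking receptors, interferon response, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis and MYC targets, apoptosis regulators, immediate early genes, replication-dependent histones, CD4 and CD8 lineage, and gamma delta T, NK and NKT, B, myeloid, erythroid and platelet cells. Each list with at least 5 tested members was tested by camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. No list call held with an estimated correlation in any of the 5 comparisons. The rotation test fry, which asks whether a list's genes move on balance in one direction, called 3, 0, 15, 9 and 1 lists in the order of the report.

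The rule named Wapl, the 6 largest called rises and falls with a mean of at least 5 CPM and no overlap between groups, up to 4 members with the smallest p of each list called by camera and of the cohesin list, a fixed set of landmark genes, and called interaction genes among these. Gene symbols without a name (such as those starting with Gm), receptor segments and small RNA genes were left out of the largest changes. The text covers the called genes of the rule, except a few that are not reported here, and part of those not called. Which of the latter were covered was chosen after their values were seen, as were Rnf43, Gm33707, Gm42427 and Gm10524.

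Whether same-numbered libraries of different groups deviate together was checked on their residuals. They did between syngeneic WT and KO (r from 0.17 to 0.545), so there the numbers were taken to pair libraries, which the labels do not state, and blocked values are given for named genes of the syngeneic comparison and the interaction whose call they change. Pairs with unlike numbers in these groups ran from −0.501 to 0.363. Syngeneic WT replicate 2 went more with KO replicate 3 (0.363) than with KO replicate 2 (0.17), so the residuals do not settle the pairing. For other group pairs the residuals did not all go together (lowest r −0.317), and the numbers were taken as shared names. The summed CPM of 4 Y-linked genes nevertheless had the same order by replicate number in both KO groups. It was 32.3, 99.4 and 116 in syngeneic KO and 31.4, 70.1 and 138 in allogeneic KO. Same-numbered KO libraries may therefore share donors, which the labels do not state. The main fit treats them as independent. The alternatives were RLE scaling, no filter on low counts, DESeq2, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and, for lists, an estimated correlation and fry. Leaving out 4 ribosomal RNA genes and a block within the syngeneic libraries were added after seeing the data.

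The procedure was tested on simulated data of 18447 genes, with 200 changed genes drawn from those above a low expression limit. The other glycolysis genes were raised as well and counted as changed. Counts were simulated independently for each gene, so structure shared by the genes of a library was left out. The procedure recovered 54% of 2-fold and 95% of 4-fold changes for KO against WT after syngeneic transplantation, 66 and 96% after allogeneic transplantation, 63 and 91% between allogeneic and syngeneic WT, 59 and 95% in KO, and 24 and 75% for the interaction. Of the calls, 5.88, 4.52, 5.65, 5.08 and 7.27% were false in the same order.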

Results

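The series measured RNA by total RNA sequencing in splenic T cells from mice with intact Wapl (WT) or lacking it (KO), 7 days after haematopoietic stem cell transplantation. Wapl releases cohesin, the ring complex that holds DNA loops and sister chromatids, from chromosomes. Donor T cells came from syngeneic recipients or from allogeneic recipients, whose tissue antigens donor T cells recognise as foreign. The 12 libraries used formed 4 groups of 3: syngeneic WT, syngeneic KO, allogeneic WT and allogeneic KO. Each library pooled 2 to 4 mice. Total counts per library ran from 45965659 to 89007100, and 18447 genes were tested. The sort kept live cells positive for CD3, part of the T cell receptor, and for the donor marker CD45.2.

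The targeted gene, Wapl (ENSMUSG00000041408, listed under the older symbol Wapal, GRCm38 chromosome 14, 34673928 to 34747983, plus strand), was measured in every library first. It stood at 187.8 ± 20.8 CPM in syngeneic WT, 134.6 ± 6.29 in syngeneic KO, 161.0 ± 6.80 in allogeneic WT and 140.0 ± 14.6 in allogeneic KO (SD, n = 3 each). Wapl fell in syngeneic KO, with a log2 fold change of −0.48 ± 0.11 (SE) and an edgeR adjusted p of 0.0368. With the replicate number as a block, its adjusted p was 0.0602. The call was also lost without syngeneic WT replicate 2 or 3 or without syngeneic KO replicate 1, 2 or 3, at adjusted p of 0.198, 0.109, 0.0918, 0.114 and 0.0869 in that order. In allogeneic KO its log2 fold change was −0.20 ± 0.11 (adjusted p = 0.963). The labels do not say which exons were deleted, and counts over the whole gene can keep reads outside the deleted part, so these levels do not measure how complete the loss was. Wapl did not pass the test between allogeneic and syngeneic libraries, with log2 fold changes of −0.22 ± 0.11 in WT (adjusted p = 0.153) and 0.06 ± 0.11 in KO (adjusted p = 0.750).

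**Figure D1:**
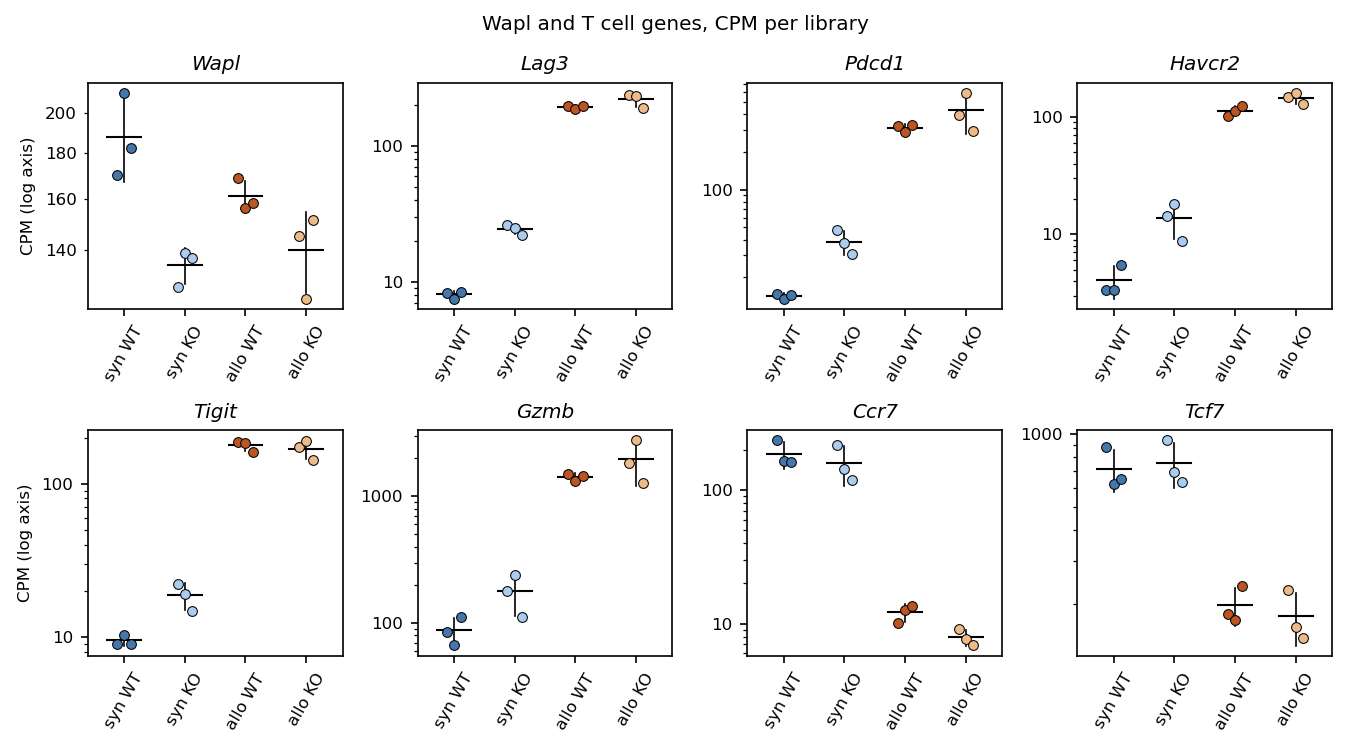
Expression of Wapl and 7 T cell genes in CPM (counts scaled by library size, log axis) in the 12 libraries; points are libraries, horizontal lines group means and vertical lines ± 1 SD, n = 3 per group. Lag3 lay at 8.04 CPM in syngeneic WT, 24.4 in syngeneic KO, 193 in allogeneic WT and 220 in allogeneic KO.

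Allogeneic and syngeneic libraries separated on the first principal component, which held 50.1% of the variance of log2 CPM. Syngeneic KO replicate 1 stood apart on the second component (18.2% of the variance), at 99.9 against 30.1 for the next library. Counts assigned to 4 ribosomal RNA genes took 21.7 ± 1.48% of a library in syngeneic WT, 26.7 ± 4.68% in syngeneic KO, 11.8 ± 5.22% in allogeneic WT and 16.9 ± 1.01% in allogeneic KO (SD, n = 3). Syngeneic KO replicate 1 had the highest share, 32.1%. Genes of the erythroid list, markers of red cell precursors, took 0.474 ± 0.208% of counts in syngeneic WT, 0.0118 ± 0.00979% in syngeneic KO, 0.00915% in allogeneic WT and 0.00758% in allogeneic KO. The summed CPM of 4 Y-linked genes was between 0.733 and 1.75 in the 6 WT libraries and between 31.4 and 138 in the 6 KO libraries. The labels name female C57BL/6 donors and give no separate sex for the Wapl KO donors.

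**Figure D2:**
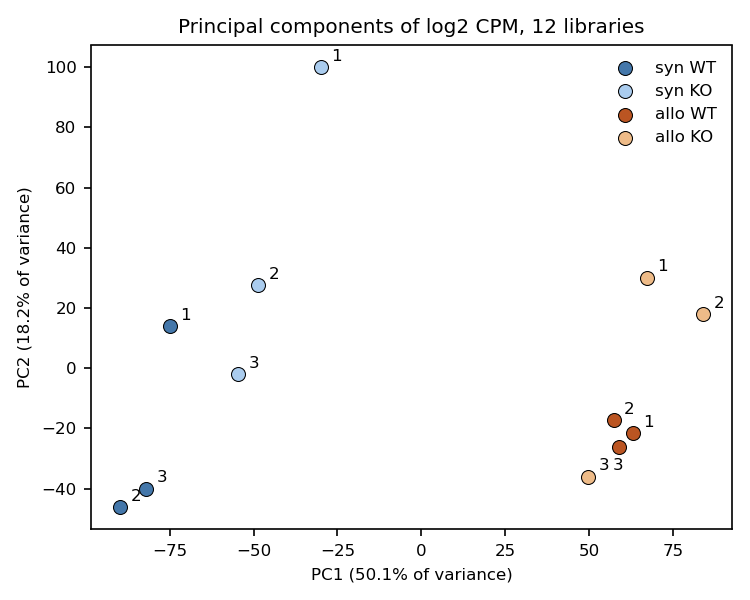
Principal components 1 and 2 of log2 CPM over the tested genes; each point is a library with its replicate number, coloured by group, and the axes give the share of variance. The allogeneic libraries lie at 49.6 or higher on the first component and the syngeneic libraries at −29.9 or lower.

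The comparison of KO with WT after syngeneic transplantation asked what loss of Wapl changed in donor T cells that meet no foreign tissue. Several inhibitory receptors of activated T cells rose in KO (n = 3 per group, log2 fold change ± SE). Lag3, which binds MHC class II, rose by 1.60 ± 0.12 (adjusted p = 4.08e-05), from 8.04 ± 0.471 to 24.4 ± 2.04 CPM. Pdcd1, which encodes PD-1, rose by 1.43 ± 0.22 (adjusted p = 0.00319). Havcr2, which encodes TIM-3, rose by 1.75 ± 0.25 (adjusted p = 0.00210, and 0.121 with the block within the syngeneic libraries described below), and Tigit rose by 0.98 ± 0.15. Lag3 lies on chromosome 6 (124904361 to 124911705, minus strand), Pdcd1 on chromosome 1 (94038305 to 94052553, minus strand) and Havcr2 on chromosome 11 (46454935 to 46481255, plus strand). All of these stayed far below their allogeneic levels, where Pdcd1 was at 312 ± 21.7 CPM in WT against 38.4 ± 8.49 in syngeneic KO.

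In this comparison edgeR called 137 genes higher and 485 lower in syngeneic KO (adjusted p under 0.05; 2578 genes had an unadjusted p under 0.05). DESeq2 called 1018. All 3 libraries of one group lay above all 3 of the other for 23.3% of tested genes, where chance gives 10%. Fitted on the 6 syngeneic libraries alone without a block, 344 genes were called, 70 higher and 274 lower. With the replicate number as a block within the 6 syngeneic libraries, chosen after seeing the data, 1324 genes were called, 396 higher and 928 lower, and 541 of these were among the 622. The count was 267 without syngeneic WT replicate 2, 281 without syngeneic WT replicate 3, 401 without syngeneic KO replicate 1 and 274 without syngeneic KO replicate 2. The 6 syngeneic libraries also differ in a label: the syngeneic KO libraries are marked syngeneic in one field and name the allogeneic recipient strain in another. They were grouped by the first field.

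Of the inhibitory receptor list, 5 of 14 tested members rose (7 adjusted over the list alone), and camera called the list up (adjusted p = 3.95e-05, and adjusted p = 0.328 with an estimated correlation). Of the effector and cytotoxic list, 3 of 25 rose (9 adjusted over the list alone), with an adjusted p = 9.30e-07, and adjusted p = 0.328 with an estimated correlation. Its risen members were Gzmk, a granzyme (1.97 ± 0.29), Prdm1, the transcription factor Blimp-1 (1.03 ± 0.17), and Ccl3, a chemokine (1.43 ± 0.35, adjusted p = 0.0443). Gzmb, the main cytotoxic granzyme, had a log2 fold change of 1.02 ± 0.30 and was not called (adjusted p = 0.114), nor were Ifng (0.69 ± 0.40), Prf1, which encodes perforin (0.31 ± 0.18), or Lgals1 (0.99 ± 0.27). DESeq2 called Gzmb (adjusted p = 0.0209) and Lgals1 (0.00774). Of the regulatory T cell list, 2 of 14 rose (3 adjusted over the list alone), Il10, an inhibitory cytokine (2.10 ± 0.49), and Nrp1 (0.61 ± 0.13), with an adjusted p = 0.00568, and adjusted p = 0.516 with an estimated correlation. Tnfrsf9 was at 0.95 ± 0.24 (adjusted p = 0.0551; 0.00701 by DESeq2). Of 19 tested p53 targets, Cdkn1a, the cell cycle inhibitor p21, rose by 1.02 ± 0.23; 2 members rose and 1 fell (3 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.833, median 0.12, mean −0.13, direction up).

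Lists of growth and metabolism were called up by camera. Of their 149 tested members edgeR called 0 over all genes (20 had an unadjusted p under 0.05), and DESeq2 called 3, among them Gapdh (adjusted p = 0.00775) and Tpi1 (0.0278). Adjusted over the list alone, 10 of 20 glycolysis genes passed, and Gapdh (0.68 ± 0.18, adjusted p = 0.0612; 0.0302 with the replicate block) and Tpi1 (0.72 ± 0.21, adjusted p = 0.0964) had the smallest p. The lists were glycolysis (adjusted p = 0.00190), oxidative phosphorylation (7.92e-04), cholesterol synthesis (0.00375), ribosome biogenesis and MYC targets (4.54e-04), replication-dependent histones (0.00190) and S phase (0.0265). With an estimated correlation the adjusted p was 0.653 for the first 5 and 0.688 for S phase. G2/M (adjusted p = 0.0413) and trafficking receptors (0.0413) were also called up, and the naive T cell list was called down (0.0413); with the replicate block these became 0.0618, 0.0632 and 0.0594, and with an estimated correlation the adjusted p was 0.697, 0.653 and 0.653. Mki67, a proliferation marker, had a log2 fold change of −0.45 ± 0.25 (adjusted p = 0.443), and Cxcr3, a chemokine receptor, 0.61 ± 0.17 (adjusted p = 0.0856; 0.0278 by DESeq2). Cohesin and its regulators were not called (adjusted p = 0.758, median 0.01, mean −0.002, direction down), and Wapl was the single member that fell. Other lists not called were type 2 helper (0.263; 1 member higher adjusted over the list alone), type 17 helper (0.518; 1 of 9 rose, 1 adjusted over the list alone) and interferon response (0.208; 1 of 25 fell, 2 adjusted over the list alone, median 0.05, mean −0.09 and direction down). Apoptosis regulators (0.121; 2 of 19 rose and 1 fell, 4 and 1 adjusted over the list alone), immediate early genes (0.0632; 1 higher adjusted over the list alone), CD4 lineage (0.441) and CD8 lineage (0.0816; 1 of 12 rose, 1 adjusted over the list alone) were not called either. Cd4 and Cd8a both had a log2 fold change of 0.24, with SE of 0.23 and 0.18.

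The falls after syngeneic transplantation included genes of red cell precursors and myeloid cells, as shown in the plot of marker genes. Hbb-bs, a beta globin (chromosome 7, 103826534 to 103828096, minus strand), fell by 6.77 ± 0.68 on the log2 scale, from 1394 ± 461 to 12.8 ± 10.4 CPM. Alas2, which starts haem synthesis in red cell precursors, fell by 6.55 ± 0.53, the globin Hba-a2 fell by 6.82 ± 0.62, and Epb42, of the red cell membrane skeleton, fell by 5.53 ± 0.51. With the block within the syngeneic libraries Hbb-bs (adjusted p = 0.0942), Alas2 (0.0522) and Hba-a2 (0.0730) were not called. In the erythroid list 11 of 15 tested members fell (14 adjusted over the list alone), and the list was called down (adjusted p = 2.73e-26, and adjusted p = 0.254 with an estimated correlation). In the myeloid list 9 of 21 fell (15 adjusted over the list alone; adjusted p = 8.87e-16, and adjusted p = 0.328 with an estimated correlation), among them the complement gene C1qa (−5.43 ± 0.88), C1qb (−4.05 ± 0.74), Siglech of plasmacytoid dendritic cells (−4.55 ± 0.71) and Cd14, a monocyte receptor (−2.91 ± 0.53). C1qa, Siglech and Cd14 were low throughout, at 2.30, 1.24 and 1.06 CPM in syngeneic WT. In the B cell list 3 of 20 fell (7 adjusted over the list alone): H2-Aa (−2.92 ± 0.61), H2-Ab1 (−2.31 ± 0.49) and Spib (−1.99 ± 0.48). Ighm and Igkc of the same list, whose values are given below, had higher means in syngeneic KO than in syngeneic WT. This list was called down (adjusted p = 1.32e-04, and adjusted p = 0.433 with an estimated correlation), and its Ebf1 was at −2.37 ± 0.62 (adjusted p = 0.0567; 0.0249 by DESeq2). The platelet list (1 of 6 fell, 2 adjusted over the list alone; Gp9 −3.09 ± 0.66) had an adjusted p = 0.00134, and adjusted p = 0.328 with an estimated correlation.

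The lists of NK and NKT cells and of gamma delta T cells were called down as well, each with 3 members past the threshold adjusted over the list alone. Their adjusted p values were 5.88e-05 and 0.00375, and the adjusted p was 0.331 and 0.328 with an estimated correlation. Klra8 was at −1.89 ± 0.49 (adjusted p = 0.0707) and Trdc, a constant segment of the gamma delta receptor, at −1.07 ± 0.31 (adjusted p = 0.0951; 0.0107 by DESeq2). The largest falls by the fixed rule also took in Apol10a (−8.11 ± 0.69), Apol11b (−7.33 ± 0.57) and Slfn14 (−7.00 ± 0.52). The largest rises took in the histone gene Hist1h4m (7.34 ± 0.52), the Y-linked genes Eif2s3y (8.63 ± 0.86), Ddx3y (8.56 ± 0.87), Uty (5.74 ± 0.75) and Kdm5d (4.90 ± 0.66), and Plcb4, a phospholipase C (3.56 ± 0.82, adjusted p = 0.0494).

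Calls of some of these named genes were lost when a single syngeneic library was left out, which also leaves fewer libraries for the test. Plcb4, Ccl3 and Il10 lost their calls without WT replicate 1, 2 or 3 or KO replicate 1 or 2 (adjusted p from 0.132 to 0.188, from 0.0597 to 0.192 and from 0.0840 to 0.164). Cdkn1a lost it without WT replicate 1 or 2 or KO replicate 1 or 2 (0.0727 to 0.141), Nrp1 without WT replicate 1 or 3 or KO replicate 1 or 3 (0.0744 to 0.0966), and Gp9 without any library but WT replicate 1 (0.0556 to 0.108). Spib and H2-Aa lost it without WT replicate 2 or 3 or KO replicate 1 or 2 (0.105 to 0.188 and 0.0530 to 0.114), H2-Ab1 without WT replicate 2 or 3 or KO replicate 2 (0.0863 to 0.0978), and C1qb without KO replicate 2 (0.0596). With the replicate block, Cdkn1a (adjusted p = 0.0559), Plcb4 (0.0595) and Ccl3 (0.0924) were not called. With the block within the syngeneic libraries, Slfn14 (0.0502), Plcb4 (0.202) and Ccl3 (0.368) were not called, while Lgals1 (0.00130), Mki67 (0.0377), Trdc (0.00110), Tpi1 (0.00194), Gapdh (0.00258), Klra8 (0.0334), Tnfrsf9 (7.05e-04) and Cxcr3 (0.00739) were. Fitted on the syngeneic libraries alone without a block, Cd14 (0.0512), C1qb (0.0638), H2-Aa (0.12), H2-Ab1 (0.147), Spib (0.0958), Cdkn1a (0.0958), Plcb4 (0.0953), Ccl3 (0.208), Il10 (0.0958), Nrp1 (0.0924) and Ifi208 (0.0930) were not called, while Trdc (0.0146), Tpi1 (0.0205) and Tnfrsf9 (0.0105) were. Without a filter H2-Aa (0.0697), H2-Ab1 (0.0638), Plcb4 (0.12) and Ccl3 (0.113) were not called and Ebf1 (0.0475) and Gapdh (0.0458) were, and without ribosomal RNA genes Ccl3 (0.0516) was not.

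**Figure D3:**
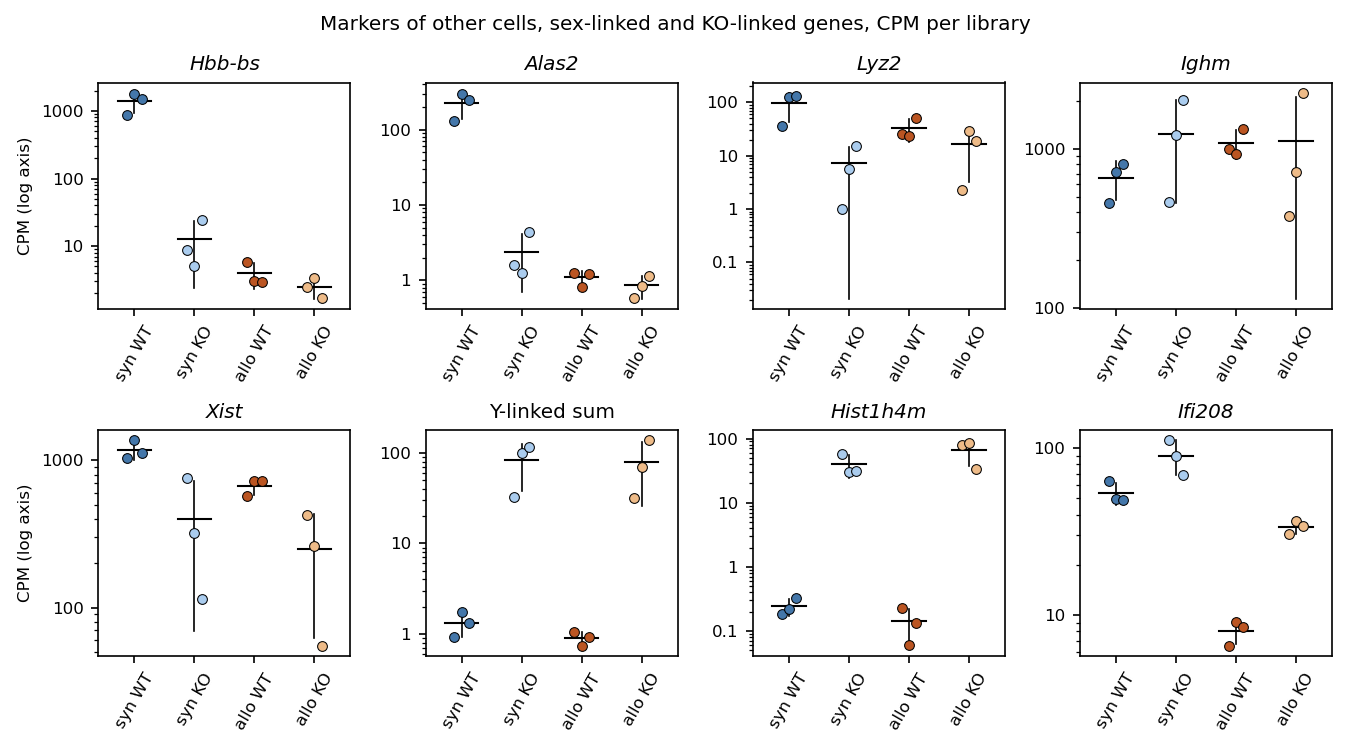
Expression in CPM (log axis) of red cell precursor genes (Hbb-bs, Alas2), the myeloid gene Lyz2, the immunoglobulin gene Ighm, Xist, the sum of 4 Y-linked genes, and Hist1h4m and Ifi208; points are libraries, horizontal lines group means and vertical lines ± 1 SD, n = 3 per group. Hbb-bs lay at 1394 CPM in syngeneic WT and at 12.8, 3.94 and 2.52 CPM in syngeneic KO, allogeneic WT and allogeneic KO.

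The comparison of KO with WT after allogeneic transplantation asked the same in donor T cells responding to foreign tissue. Few genes passed the edgeR threshold (n = 3 per group), which does not measure how many changed. Hist1h4m, a replication-dependent histone H4 gene (chromosome 13, 21811746 to 21812147, plus strand), rose by 8.97 ± 0.56 (adjusted p = 5.72e-05), from 0.141 to 65.9 CPM. Ifi208, of the interferon-inducible Ifi200 family (chromosome 1, 173673675 to 173698395, plus strand), rose by 2.07 ± 0.19 (adjusted p = 5.48e-04), from 8.02 ± 1.31 to 33.7 ± 2.90 CPM. Histone H4 and Ifi200 genes have near-identical copies, so their counts can include shared reads. The Y-linked genes Ddx3y (9.74 ± 0.96), Eif2s3y (9.51 ± 0.90), Uty (6.40 ± 0.77) and Kdm5d (5.19 ± 0.67) also rose, against 0.0262, 0.0296, 0.112 and 0.727 CPM in allogeneic WT.

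EdgeR called 8 genes higher and 2 lower (771 had an unadjusted p under 0.05), while DESeq2 called 77. Groups did not overlap for 7.66% of tested genes, where chance gives 10%. The other called genes, named because the count is small and chosen after their values were seen, were Rnf43 (1.01 ± 0.13), the pseudogene Gm33707 (1.09 CPM in KO and 0.00339 in WT), Gm42427 (−1.08 ± 0.14) and Gm10524 (−0.73 ± 0.11). Without allogeneic WT replicate 1, 2 or 3 the count was 3 each time (1042, 419 and 666 at an unadjusted p under 0.05), and without allogeneic KO replicate 3 it was 15 (2300). Ddx3y, Eif2s3y, Rnf43 and Gm42427 lost their calls without allogeneic WT replicate 1, 2 or 3 (adjusted p from 0.0682 to 0.113, from 0.0587 to 0.0868, from 0.0682 to 0.167 and from 0.0710 to 0.135). Kdm5d (0.127 to 0.377) and Uty (0.0546 to 0.167) lost theirs without the same WT libraries and without KO replicate 2, and Gm10524 without any library of either group (0.0593 to 0.345). Fitted on these groups alone, Kdm5d (0.0642), Rnf43 (0.202), Gm42427 (0.202) and Gm10524 (0.379) were not called, nor were Kdm5d (0.103), Uty (0.0542) and Gm10524 (0.0577) without a filter, or Gm10524 with the replicate block (0.0713). Gm10524 overlaps exons of Zfp236 on the opposite strand, and the strand setting of the counts is not given.

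Of 488 tested members of the 27 lists edgeR called 0 over all genes in this comparison (53 had an unadjusted p under 0.05), so the following are values. DESeq2 called 5, among them Maf (adjusted p = 0.0129), Satb1 (0.0106), Egr2 (0.0248) and Egr3 (0.0106). Gzmb had a log2 fold change of 0.46 ± 0.30, Ifng 0.32 ± 0.39, Prf1 0.41 ± 0.18, Pdcd1 0.46 ± 0.21 and Tox, a factor of exhausted T cells, 0.45 ± 0.12 (adjusted p = 0.473 for Tox and 0.963 for the others). Camera called replication-dependent histones (adjusted p = 7.89e-11), S phase (3.53e-09), G2/M (3.53e-09), oxidative phosphorylation (0.00169), effector and cytotoxic genes (0.00505), cholesterol synthesis (0.00505), cohesin and its regulators (0.00993), glycolysis (0.0139), inhibitory receptors (0.0240) and CD8 lineage (0.0240) up. With an estimated correlation the adjusted p was 0.675 for oxidative phosphorylation and 0.673 for each of the others. Examples were Hist1h1a (0.82 ± 0.31), Cdk1 (0.53 ± 0.24), Top2a (0.42 ± 0.17), the cohesin subunit Stag2 (0.27 ± 0.13) and Cd8a (0.38 ± 0.18), each at an adjusted p of 0.963. Type 2 helper (adjusted p = 4.68e-05), naive (0.00125), CD4 lineage (0.00222), myeloid (0.00614) and immediate early (0.00649) lists were called down. For these the adjusted p = 0.552 with an estimated correlation for type 2 helper and 0.673 for the others. Adjusted over the list alone, 4 of 10 type 2 helper genes, 2 of 20 immediate early genes and 1 of 20 naive genes were lower, and 1 of 14 inhibitory receptor genes was higher. Maf, a factor of interleukin expression, was at −0.69 ± 0.16 (adjusted p = 0.307), Il13 at −1.09 ± 0.36, Egr2 at −0.62 ± 0.16 (0.437), Egr3 at −0.70 ± 0.17 (0.404), Satb1 at −0.52 ± 0.13 (0.437), Ccr7 at −0.62 ± 0.23 and Cd4 at −0.39 ± 0.23.

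Of the called genes, 9 passed in both KO comparisons in the same direction. They were 8 higher genes, where independent lists would share 0.0594, and 1 lower gene, where they would share 0.0526. These were the 4 Y-linked genes, Hist1h4m, Ifi208, Rnf43 and Gm33707, and, lower, Gm42427. After syngeneic transplantation Ifi208 rose by 0.74 ± 0.18 (adjusted p = 0.0374, and 0.0536 with the replicate block), Rnf43 rose by 0.80 ± 0.13, and Gm42427 fell by 1.01 ± 0.14. Ifi208 lost its call there without syngeneic WT replicate 2 or 3 or syngeneic KO replicate 1 or 2 (adjusted p from 0.116 to 0.191). Across 18447 genes, which are not independent replicates, the KO effects in the 2 settings had a Pearson r of 0.325 and a Spearman rho of 0.330. The settings have separate WT libraries, but same-numbered KO libraries may share donors.

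The comparison of allogeneic with syngeneic libraries in WT described the donor T cell response to foreign tissue, together with the recipient strain, the irradiation (8 against 9.5 Gy) and the donor T cell dose (8.5 times as high in syngeneic recipients), which differed as well. Allogeneic T cells carried high levels of effector genes and inhibitory receptors (n = 3 per group). Gzma, a granzyme, rose by 5.78 ± 0.39 (adjusted p = 6.58e-07), from 20.7 ± 4.56 to 1136 ± 223 CPM, and Gzmb rose by 4.03 ± 0.34. Lag3 rose by 4.59 ± 0.13 (adjusted p = 6.98e-10), Havcr2 by 4.80 ± 0.28, Pdcd1 by 4.45 ± 0.25 and Tigit by 4.23 ± 0.17. Genes of naive T cells fell, among them Ccr7, a lymph node chemokine receptor (−3.94 ± 0.25, from 186 to 12.2 CPM).

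EdgeR called 3023 genes higher and 2932 lower in allogeneic WT, and groups did not overlap for 55.7% of genes, where chance gives 10%. Effector and cytotoxic genes (21 of 25 rose and 1 fell; 22 and 2 adjusted over the list alone) also included Prf1 (2.44 ± 0.19), Ifng (2.02 ± 0.41), Tbx21 (1.54 ± 0.17), Cx3cr1 (3.87 ± 0.19), Id2 (2.57 ± 0.14) and Prdm1 (2.82 ± 0.18), while Eomes fell (−1.26 ± 0.16). Their camera adjusted p was 3.83e-13, and the adjusted p = 0.189 with an estimated correlation. Inhibitory receptors (9 of 14 rose; 9 adjusted over the list alone) had an adjusted p = 9.12e-07, and adjusted p = 0.189 with an estimated correlation. Type 2 helper genes (7 of 10 rose and 1 fell; 7 and 1 adjusted over the list alone) included Il13 (5.81 ± 0.47), Il1rl1 (3.23 ± 0.27), Maf (2.95 ± 0.17) and Gata3 (1.78 ± 0.16). Type 17 helper genes (4 of 9 rose; 5 and 1 lower adjusted over the list alone) included Ahr (3.10 ± 0.20), Il21 (2.23 ± 0.38), Rora (2.10 ± 0.24) and Batf (2.18 ± 0.29). These lists had adjusted p of 6.23e-04 and 0.0139, and adjusted p = 0.189 with an estimated correlation for both. Trafficking genes (15 of 20 rose and 1 fell; 15 and 1 adjusted over the list alone) included Cxcr6 (3.00 ± 0.29), Itga2 (1.85 ± 0.19), Itgb1 (1.76 ± 0.14) and Itga4 (1.69 ± 0.17), and apoptosis regulators (13 of 19 rose and 1 fell; 13 and 2 adjusted over the list alone) included Bcl2a1d (2.80 ± 0.28), Pmaip1 (2.22 ± 0.15) and Bak1 (1.11 ± 0.12). Their adjusted p was 9.12e-07 and 3.46e-05, and adjusted p = 0.189 with an estimated correlation for both.

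Regulatory T cell genes (7 of 14 rose and 2 fell; 7 and 2 adjusted over the list alone) included Il10 (3.64 ± 0.51), Nrp1 (2.89 ± 0.14), Il2ra (2.195 ± 0.185) and Tnfrsf9 (2.02 ± 0.25), with an adjusted p = 0.0186, and adjusted p = 0.621 with an estimated correlation. Glycolysis (10 of 20 rose and 3 fell; 13 and 3 adjusted over the list alone; adjusted p = 0.0139) included the glucose transporter Slc2a3 (1.46 ± 0.10) and Pfkp (0.81 ± 0.13) among the rises and Pdk1 (−2.31 ± 0.19) and P4ha1 (−1.18 ± 0.16) among the falls. G2/M genes (5 of 30 rose; 5 adjusted over the list alone; adjusted p = 0.00557) included Cdc25c (0.95 ± 0.20), Ccnb2 (0.90 ± 0.19), Cdc20 (0.77 ± 0.20) and Cenpa (0.75 ± 0.15). The adjusted p was 0.669 for both with an estimated correlation. Mki67 was at −0.28 ± 0.25 (adjusted p = 0.420). Oxidative phosphorylation (adjusted p = 0.0151; 2 of 25 rose but none adjusted over the list alone, among them Cox5a, 0.68 ± 0.22) and replication-dependent histones (0.0160) were called up, both at adjusted p = 0.698 with an estimated correlation. In the cohesin list, not called (adjusted p = 0.720), 2 of 19 rose (2 adjusted over the list alone), Pttg1 (0.68 ± 0.16) and Rad21 (0.51 ± 0.15). Cd4 rose by 1.08 ± 0.23, Cd8a fell by 0.63 ± 0.18, Cd44 rose by 0.80 ± 0.12 and Cdkn1a rose by 1.17 ± 0.23. Cd8a and Rad21 lost their calls without syngeneic WT replicate 1 or allogeneic WT replicate 1 (adjusted p from 0.0789 to 0.0841 and from 0.0672 to 0.0878), Cdc20 without allogeneic WT replicate 1 (0.0606), and Cox5a without syngeneic WT replicate 2 or 3 or allogeneic WT replicate 1 (0.0750 to 0.126).

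Naive T cell genes (14 of 20 fell and 1 rose; 14 and 1 adjusted over the list alone) also included Dapl1 (−5.10 ± 0.36), Bach2 (−3.12 ± 0.25), Tcf7 (−1.87 ± 0.22) and the survival gene Bcl2 (−0.94 ± 0.13), with an adjusted p = 8.13e-06, and adjusted p = 0.417 with an estimated correlation. Interferon response genes (11 of 25 fell and 1 rose; 11 and 1 adjusted over the list alone) included Rsad2 (−4.43 ± 0.33), Usp18 (−2.09 ± 0.31), Oasl1 (−1.93 ± 0.23) and Oasl2 (−1.85 ± 0.27). Ribosome biogenesis genes (11 of 25 fell; 13 adjusted over the list alone) included the growth regulator Myc (−1.21 ± 0.15), Odc1 (−1.05 ± 0.19), Utp20 (−0.91 ± 0.15) and Polr1b (−0.73 ± 0.11). These lists had adjusted p of 0.00180 and 9.47e-04, and adjusted p = 0.669 with an estimated correlation for both. The erythroid list fell in 14 of 15 members (14 adjusted over the list alone; adjusted p = 1.12e-10, and adjusted p = 0.256 with an estimated correlation), led by Hbb-bs (−8.47 ± 0.73), Hba-a2 (−8.32 ± 0.67), Hba-a1 (−7.91 ± 0.81), Alas2 (−7.69 ± 0.57) and Epb42 (−6.63 ± 0.54). Erythroid genes took 0.474% of counts in syngeneic WT and 0.0118% in syngeneic KO. Between allogeneic and syngeneic KO edgeR called 2 of the 15. These falls follow the syngeneic WT libraries and need not belong to the response to foreign tissue. The B cell list fell in 9 of 20 (9 adjusted over the list alone; adjusted p = 0.00459, and adjusted p = 0.621 with an estimated correlation), with Ly6d (−3.17 ± 0.55), Spib (−2.84 ± 0.50), Bank1 (−2.25 ± 0.41) and Cd22 (−1.46 ± 0.16). By the fixed rule the largest falls added Slfn14 (−9.00 ± 0.59), Tmcc2 (−8.10 ± 0.57) and Ypel4 (−7.91 ± 0.67), and the largest rises were Dpysl3 (6.87 ± 0.63), the NK receptor gene Klrb1b (6.56 ± 0.52), Epha3 (6.51 ± 1.19), Serpinb9b (5.91 ± 0.42), Gldc (5.83 ± 0.28) and Erc2, which stood at 5.32 CPM in allogeneic and 0.00570 in syngeneic WT.

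The same comparison in KO, added after the data were seen, asked how allogeneic and syngeneic T cells differed without Wapl. The same receptors and granzymes were higher in allogeneic libraries (n = 3 per group). Gzma rose by 5.69 ± 0.39 (adjusted p = 9.71e-07), Gzmb by 3.47 ± 0.33, Pdcd1 by 3.48 ± 0.24, Havcr2 by 3.40 ± 0.26, Lag3 by 3.18 ± 0.12 and Tigit by 3.18 ± 0.16. Ccr7 (−4.34 ± 0.25), Tcf7 (−2.09 ± 0.22), Bach2 (−2.98 ± 0.25) and Dapl1 (−4.53 ± 0.35) fell. EdgeR called 2439 genes higher and 2061 lower, and groups did not overlap for 33.6% of genes, where chance gives 10%. Genes called in both genotypes numbered 2007 higher (independent lists would share 399.7) and 1564 lower (327.6), with a Pearson r of 0.769 across genes.

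In KO, effector and cytotoxic genes (20 of 25 rose and 2 fell; 21 and 2 adjusted over the list alone) included Cx3cr1 (4.41 ± 0.20), Prf1 (2.54 ± 0.19), Id2 (2.09 ± 0.13), Ifng (1.65 ± 0.40) and Tbx21 (1.16 ± 0.16) among the rises and Eomes (−1.14 ± 0.16) among the falls. Effector, inhibitory (9 of 14 rose; 9 adjusted over the list alone), trafficking (13 of 20 rose; 15 adjusted over the list alone; Itga1 5.07 ± 0.53, Cxcr6 2.99 ± 0.29, Itga4 1.73 ± 0.17, Itgb1 1.31 ± 0.14) and type 17 lists (5 of 9 rose; 6 adjusted over the list alone; Ahr 2.50 ± 0.20, Il23r 2.06 ± 0.62, Rora 2.00 ± 0.24, Batf 1.57 ± 0.28) were called up. Their adjusted p was 8.21e-13, 1.15e-06, 1.06e-06 and 0.00341, and with an estimated correlation the adjusted p was 0.171, 0.220, 0.171 and 0.171. Also called up were apoptosis regulators (12 of 19 rose; 13 adjusted over the list alone; Pmaip1 2.00 ± 0.14, Bcl2l11 1.17 ± 0.16, Apaf1 0.82 ± 0.11), type 2 helper (7 of 10 rose and 2 fell; 7 and 2 adjusted over the list alone; Il1rl1 3.76 ± 0.28, Il13 3.65 ± 0.42, Maf 1.69 ± 0.16, Il4ra −1.54 ± 0.15) and G2/M genes (9 of 30 rose; 19 adjusted over the list alone; Cenpa 0.97 ± 0.15, Ccnb2 0.96 ± 0.19, Cdc25c 0.89 ± 0.20, Birc5 0.78 ± 0.21). Their adjusted p was 1.40e-05, 0.00289 and 2.32e-05, and with an estimated correlation the adjusted p was 0.175, 0.312 and 0.736. Replication-dependent histones (5 of 27 rose but none adjusted over the list alone; Hist1h2bj 0.90 ± 0.26, Hist1h2bk 0.88 ± 0.29, Hist1h1b 0.83 ± 0.28, Hist1h1e 0.74 ± 0.21) and myeloid genes (3 of 21 rose; 3 adjusted over the list alone; Itgam 3.02 ± 0.50, Cd14 1.86 ± 0.54, Cst3 1.03 ± 0.21) were called up at adjusted p of 6.40e-04 and 0.00429. With an estimated correlation the adjusted p was 0.785 and 0.736.

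Lists called down in KO were naive T cell genes (14 of 20 fell and 1 rose; 14 and 1 adjusted over the list alone), ribosome biogenesis (14 of 25 fell; 19 adjusted over the list alone; Myc −1.30 ± 0.15, Polr1b −1.08 ± 0.11, Utp20 −1.02 ± 0.15, Ppan −0.73 ± 0.12) and interferon response (11 of 25 fell; 14 adjusted over the list alone; Usp18 −1.92 ± 0.31, Oasl1 −1.79 ± 0.23, Oasl2 −1.51 ± 0.27, Ifit2 −0.92 ± 0.17). Their adjusted p was 7.15e-07, 2.01e-07 and 6.55e-04, and with an estimated correlation the adjusted p was 0.352, 0.460 and 0.736. In the cohesin list (adjusted p = 0.0949) Pttg1 (0.60 ± 0.16) and Rad21 (0.58 ± 0.15) rose. Il2ra (1.86 ± 0.18), Cd44 (0.73 ± 0.12) and Mdm2 (0.34 ± 0.09) rose, Il2 (−1.25 ± 0.38) and Bcl2 (−1.03 ± 0.13) fell, and Cd4 (0.44 ± 0.23, adjusted p = 0.182) and Cd8a (−0.49 ± 0.18, adjusted p = 0.0708; 0.0444 by DESeq2) were not called. Besides Gzma, the largest changes by the fixed rule were rises of Klrb1b (8.19 ± 0.56), Erc2 (7.00 ± 0.54), Gldc (6.40 ± 0.30), Dpysl3 (6.16 ± 0.61) and Chil3 (5.60 ± 1.10) and falls of Dntt (−6.28 ± 0.32), Slc16a5 (−5.54 ± 0.32), Slc6a19 (−5.34 ± 0.29), Sh3pxd2a (−4.92 ± 0.14), Tmem108 (−4.88 ± 0.35) and Trim30c (−4.88 ± 0.31).

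Some calls between the KO groups were lost when a single library was left out. Without syngeneic KO replicate 2 or 3, Pttg1 lost its call (adjusted p from 0.0633 to 0.0640), as did, without these or allogeneic KO replicate 1, Rad21 (0.0571 to 0.0625) and Hist1h1e (0.0706 to 0.108). Birc5 (0.0506 to 0.0815), Hist1h1b (0.127 to 0.151), Hist1h2bk (0.106 to 0.154) and Hist1h2bj (0.0712 to 0.0832) lost theirs without syngeneic KO replicate 2 or 3 or allogeneic KO replicate 1 or 2. Il23r lost it without syngeneic KO replicate 2 or 3 or allogeneic KO replicate 3 (0.0637 to 0.0995), Cd14 without syngeneic KO replicate 1 or 2 or allogeneic KO replicate 2 or 3 (0.0526 to 0.0625), and Il2 without replicate 1 or 3 of either group (0.0574 to 0.0741). Fitted on the libraries of these groups alone, 2659 genes were called. Mdm2 (adjusted p = 0.0753), Il2 (0.0911), Ifng (0.0729), Chil3 (0.0504), Pttg1 (0.0696), Rad21 (0.0609), Cd14 (0.0552), Hist1h1e (0.0619), Hist1h1b (0.0874), Hist1h2bk (0.0761) and Hist1h2bj (0.0557) were then not called. Without a filter Il2 (0.0585), Hist1h1b (0.0756) and Hist1h2bk (0.0905) were not called, and with the replicate block Hist1h1b (0.0516) and Hist1h2bk (0.0765) were not and Cd4 (0.0270) was.

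The interaction asked whether the KO effect differed between allogeneic and syngeneic transplantation (n = 3 per group, KO effect in allogeneic minus that in syngeneic libraries). It was lower for Lag3 (−1.41 ± 0.16, adjusted p = 0.00291) and for Zbtb32, a repressor of effector T cells (−1.21 ± 0.17, adjusted p = 0.00691). For Pdcd1 (−0.97 ± 0.31, adjusted p = 0.347), Havcr2 (−1.40 ± 0.34, 0.145) and Tigit (−1.05 ± 0.21, 0.0541) the difference was not called by edgeR. DESeq2 called Havcr2 (adjusted p = 0.0124) and Tigit (7.72e-04), and Tigit was also called with RLE scaling (0.0449), without a filter (0.0341), with the replicate block (0.0323) and without ribosomal RNA genes (0.0495). It was higher for genes of red cell precursors, such as Alas2 (6.26 ± 0.72) and Epb42 (5.78 ± 0.69), which had fallen in syngeneic KO. EdgeR called 79 genes with a higher and 9 with a lower KO effect in allogeneic libraries (1144 at an unadjusted p under 0.05), and DESeq2 called 293. With the replicate block 64 were called, 51 of them among the 88. Erythroid genes made up 8 of the 79 (14 of 15 adjusted over the list alone; adjusted p = 2.30e-32, and adjusted p = 0.147 with an estimated correlation).

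Other lists with a higher KO effect in allogeneic libraries were myeloid (adjusted p = 2.96e-12), NK and NKT (2.52e-06), B cell (1.06e-04), gamma delta (0.0167), platelet (0.0459) and cohesin (0.0459; 0.0604 with the replicate block) lists. With an estimated correlation the adjusted p was 0.347, 0.347, 0.437, 0.437, 0.580 and 0.631. Adjusted over the list alone, 7 myeloid, 4 B cell, 1 NK and 1 platelet genes passed. Lists with a lower KO effect were regulatory T cell (1.44e-04), type 2 helper (4.05e-04), inhibitory receptor (0.00123), effector (0.00192) and ribosome biogenesis lists (0.00192). With an estimated correlation the adjusted p was 0.361, 0.347, 0.437, 0.580 and 0.726. Adjusted over the list alone, 3 regulatory, 3 type 2 helper, 4 inhibitory receptor and 1 effector genes passed. Wapl itself had a difference of 0.28 ± 0.16 (adjusted p = 1). The count was 239 without syngeneic WT replicate 1, 32 without syngeneic WT replicate 2, 30 without syngeneic WT replicate 3, 35 without syngeneic KO replicate 1, 32 without syngeneic KO replicate 2, 31 and 25 without allogeneic WT replicates 2 and 3, and 41, 33 and 35 without allogeneic KO replicates 1, 2 and 3. Lag3, Zbtb32 and Epb42 kept their calls without any single library, and Alas2 lost its call without allogeneic KO replicate 3 (adjusted p = 0.0591).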

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

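The tests of a lower T cell share, of the donors' sex, of DNA near Wapl and of admixed cells as the whole cause of the rises, and the grouping of interaction splits by syngeneic labels, were chosen after the results were seen. The KO effect differed between allogeneic and syngeneic transplantation, by the interaction test, for 79 genes with a higher and 9 with a lower effect in allogeneic libraries. Lower effects (log2) were found for Zbtb32 (−1.21), Ajuba (−1.55), Car5b (−1.23), Lag3 (−1.41), Maf (−1.26), Egr3 (−1.21) and Egr2 (−1.20). Higher ones were found for Cd36 (7.12), Ypel4 (6.66), Sowaha (6.76), Apol10a (8.77), Apol11b (7.56), Hbb-bt (6.43), Epb42 (5.78), Alas2 (6.26), Hbb-bs (6.13), Hba-a2 (6.11), Slfn14 (6.65) and Ifi208 (1.33). With the replicate number as a block 64 genes were called, 51 of them among the 88, and Hbb-bt (adjusted p = 0.0798), Hbb-bs (0.0534), Hba-a2 (0.0957), Slfn14 (0.0984) and Ifi208 (0.0694) were not. Without a filter Hbb-bt (0.0582), Hba-a2 (0.0741) and Slfn14 (0.0672) were not called. Lag3, Zbtb32, Cd36, Apol10a, Apol11b and Epb42 kept their calls in each of 12 fits without 1 library. Sowaha and Alas2 lost theirs without allogeneic KO replicate 3 (adjusted p = 0.0591 for both). Of the 12 libraries, Maf lost its call without 7 (0.0506 to 0.104), Ypel4 (0.0517 to 0.123) and Hbb-bs (0.0506 to 0.0750) without 6 each, Hbb-bt (0.0615 to 0.127) and Hba-a2 (0.0576 to 0.252) without 8 each, Car5b (0.0676 to 0.104), Egr2 (0.0584 to 0.122) and Slfn14 (0.0590 to 0.306) without 9 each, and Ajuba (0.0641 to 0.145), Egr3 (0.0664 to 0.182) and Ifi208 (0.0573 to 0.125) without 10 each.

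The first pattern was the falls in KO after syngeneic transplantation. A lower share of T cells in syngeneic WT libraries, raising every other cell type alike, would lower the erythroid and B cell lists by a like amount, but their medians differed by −5.04 (bootstrap interval −6.02 to −1.81). Like falls are foreseen only if the RNA of both lists comes from those other cells, which was not tested. The bootstrap over genes does not measure the spread between libraries. A candidate source that stayed open is RNA of red cell precursors in the syngeneic WT libraries, which a sort on CD3 would remove as whole cells. Over libraries within groups, the 474 called falls outside the erythroid list had a median correlation with the erythroid score of 0.516 (random lists matched on expression: median −0.0301, 95th percentile 0.00415), and Hbb-bs stood at 1394 CPM in syngeneic WT. The random lists were drawn gene by gene outside the falls and lack the shared variation of a real gene set. Passing them is therefore not specific to RNA of red cell precursors. The same falls include myeloid genes, and an effect of Wapl loss on these cells was not tested.

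The second pattern was the 9 genes called alike in both KO comparisons, of which 4 are Y-linked. Over the 6 KO libraries Xist relative to its WT mean fell with the Y-linked sum (Spearman rho = −0.943, exact permutation p = 0.0167; Pearson r = −0.989, exact permutation p = 0.00278, and −0.991 without the 2 farthest libraries), so male donors in the KO pools are a candidate source of these 4. The permutations treat the 6 libraries as independent, although same-numbered ones may share donors. Of Rnf43, Ifi208, Hist1h4m, Gm33707 and Gm42427, each relative to the WT mean of its setting, 0 followed the Y-linked sum in the direction of their call with a rho of 0.8 or more in size (rho of 0.257, −0.143, −0.6, 0.0286 and 0.0286), and 0 lay within 20 Mb of Wapl. This argues against male donors and against DNA within 20 Mb of Wapl as sources of these 5. Differences between WT and KO donors in DNA elsewhere were not tested. All KO libraries had Y-linked counts and no WT library did at that level, so the donors' sex is confounded with genotype for every KO comparison. An effect of Wapl loss on the 5 genes stayed open, untested.

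The third pattern was the rises in KO after syngeneic transplantation, whose label conflict raises the question of admixed cells of the allogeneic response. Chance low values of single genes in syngeneic WT, independent of each other, are argued against. Of 129 rises (not called in both KO comparisons), 88.4% were higher in allogeneic than in syngeneic KO, against 48.5% of all tested genes. In simulation without effects the share was 7.88%. The simulation drew each gene on its own, so a deviation shared by many genes of the syngeneic WT libraries was not tested. Admixed cells as part of the cause cannot be told apart from an effect of Wapl loss: 82.3% of 79 genes at least 8-fold higher in allogeneic WT lay above their syngeneic WT mean, between the bounds set in advance, with an implied median share of 4.03% (1.98 to 5.68%; quartiles of single genes 0.411 and 8.84%). Whether admixed cells are the whole cause of these rises was not decided. Set against allogeneic KO, the median rise would need a share of 20.8% (17.3 to 24.7%). The 79 genes implied a median of 3.49% (2.35 to 5.32%), with 5 of them at 17.3% or more. Gzma (0.483%), Csf1 (−0.0397%) and Cx3cr1 (−0.397%) lay low, while Lag3 (7.69%), Havcr2 (6.83%), Pdcd1 (5.83%), Tigit (5.78%) and Gzmb (4.77%) lay higher. The rises were selected for a large gap between syngeneic KO and WT, which raises the share they need. The 79 genes were selected for low syngeneic WT against allogeneic WT values, and their shares use the same syngeneic WT means. This tends to raise the 82.3% and the shares they imply. The 79 also include some of the rises, among them Lag3, Pdcd1 and Havcr2, so the sets compared overlap. The bootstrap over genes does not measure the spread between libraries. A stricter count, made before the comparison of shares, took genes whose highest syngeneic KO library lay below 17.3% of the lowest allogeneic KO library (Gzma 39.0 CPM against 169, Klrb1b 0.238 against 5.86). It gave 46.8% of the 79 and missed the 50% written as its bound.

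For each comparison of 3 libraries with 3, 10 splits are too few for a share under 0.05. The counts were 622 for KO against WT after syngeneic transplantation (highest other split 0; 1 of 10 splits as large), 10 after allogeneic transplantation (highest other 272; 2 of 10), 5955 between allogeneic and syngeneic WT (0; 1 of 10) and 4500 in KO (1060; 1 of 10). The split with 272 calls put allogeneic KO replicates 1 and 2 together with an allogeneic WT library, which points to a structure of the samples. For the interaction 9 of 100 splits, with the real one, called at least its 88 genes, up to 274. The 8 others as large were among 10 that left the syngeneic labels as they were, and so kept the KO effect there, while the 89 that mixed these labels called at most 9. The count of 9 therefore does not decide whether chance can be excluded.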

How the results depend on the processing

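Over the 247 results of single named genes other than Wapl, 2814 of 3123 values under the alternatives kept direction and side of the threshold, 266 lost a call, 41 gained one and 2 reversed, and 173 results kept both in every alternative. The block within the syngeneic libraries and the fits without ribosomal RNA genes were chosen after seeing the data, as was the comparison of allogeneic with syngeneic KO. For KO against WT after syngeneic transplantation (622 genes), fitting only the groups compared called 344, DESeq2 1018 and the block within the syngeneic libraries 1324, and fits without 1 library each called 267 to 698. Wapl there was not called without a filter (−0.49), with the replicate block (−0.48) or with only the groups compared (−0.52), at adjusted p of 0.0515, 0.0602 and 0.0660, and ran from −0.55 to −0.39 without single libraries. After allogeneic transplantation (10 genes) only the groups compared gave 6, DESeq2 77 and single left-out libraries 3 to 15. Between allogeneic and syngeneic KO (4500 genes) only the groups compared gave 2659, and Wapl, not called, ran from −0.003 to 0.18 without single libraries, reversed without allogeneic KO replicate 3. The interaction (88 genes) had 293 calls by DESeq2, 64 with the replicate block and 25 to 239 without single libraries. With an estimated correlation 0 lists were called in each of the 5 comparisons, and fry called 3 after syngeneic transplantation, 0 after allogeneic transplantation and 1 for the interaction. The correlation of KO effects (0.325) was 0.474 over genes with at least 5 CPM and 0.254 to 0.335 without single libraries. Cd4 after syngeneic transplantation ran from −0.006 to 0.39, reversed without syngeneic KO replicate 1, and Ifng after allogeneic transplantation from −0.092 to 0.53, reversed without allogeneic KO replicate 2. Neither was called. Fits of only the groups compared and those without a library use fewer libraries; otherwise the cause was not tested. Among the named genes the replicate block after syngeneic transplantation changed the calls of Wapl, Cdkn1a, Plcb4, Ccl3, Ifi208 and Gapdh, and for the interaction those of Hbb-bt, Hbb-bs, Hba-a2, Slfn14, Ifi208 and Tigit. The interaction uses all 4 groups, so it has no separate fit of the groups compared. The comparisons with naive samples were not run under any setting.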

Other observations

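The genes below were chosen after their values were seen, and no test of an explanation was run. Immunoglobulin transcripts were abundant in all groups. Ighm, the mu heavy chain, stood at 660 ± 180 CPM in syngeneic WT, 1242 ± 785 in syngeneic KO, 1092 ± 220 in allogeneic WT and 1120 ± 1010 in allogeneic KO (SD, n = 3). Igkc, the kappa light chain, stood at 163, 374, 418 and 408 CPM in the same order.

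Values of 6 genes of neutrophils and their precursors varied between libraries. Ngp, a granule gene of maturing neutrophils, stood at 227 ± 111 CPM in syngeneic WT, 5.21 ± 7.09 in syngeneic KO, 206 ± 70.2 in allogeneic WT and 61.4 ± 48.8 in allogeneic KO. Ltf (191, 3.76, 127 and 40.6 CPM) and S100a8 (93.8, 2.79, 78.0 and 34.0 CPM) had the same order of groups. The early granule gene Mpo stood at 121 ± 68.2, 146 ± 134, 74.96 ± 50.8 and 95.7 ± 51.5 CPM, Elane at 23.7, 18.02, 24.4 and 25.6 CPM, and Prtn3 at 31.3, 30.6, 24.5 and 26.1 CPM, all in the same group order.

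Near Wapl, 7 of 314 tested genes within 20 Mb were called after syngeneic transplantation (2.23%, against 3.37% of all tested genes; Fisher's exact test, two-sided p = 0.342).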
